A study of Rattus norvegicus with 14 samples.

How the data were processed

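Total RNA from extraocular, cardiac and leg muscle and from stomach wall freed of its epithelium, all from control adult rats, was measured on Affymetrix rat arrays with an antibody scan, per the labels. The deposited values are intensity values, 1 linear number of 0 or more per probe set and array, which had been scaled before deposit. The ratio of the highest to the lowest 2% trimmed mean of the 14 arrays was 1.0008, while that of the medians was 1.985. The program and version that made the values are not given in the sources used here. Groups came from the sample titles, with 4 extraocular, 4 cardiac, 3 leg and 3 stomach arrays. The highest number of identical values between any 2 arrays was 9, so each array counted as 1 sample.

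The table held 8799 probe sets, of which 59 were array controls and 8740 were not. The platform annotation listed 7326 of the probe sets and did not list 1473. A single gene symbol was given for 7018 and several for 308. Of the former, 6994 had their gene identifier in the reference gene table, and the unique symbols numbered 4737. Probe sets with several symbols or none were tested but not named.

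The deposited scaling was kept because the trimmed means lay within 1.2 times of each other. Values under 208.5 intensity units, the 30th percentile of all values (7.704 in log2), were set to that floor before taking log2. A probe set was tested if it lay above the floor on at least 3 arrays, which left 7331 probe sets, 5934 of them with a single symbol, for 4187 genes. These numbers set the depth of the data, since a probe set at the floor gives only a bound. R 4.3.3 and limma 3.58.1 fitted the 14 arrays with a mean per tissue (10 residual degrees of freedom, 4.02 prior degrees of freedom). Each pair of tissues was tested two-sided by moderated t statistics. A probe set was called when its Benjamini-Hochberg adjusted p was under 0.05 and its fold at least 2. For genes higher in one tissue than in each other tissue, the largest of the p-values of its 3 contrasts was adjusted, and each fold had to be at least 2.

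Lists of genes for muscle functions and for other cell types were tested with camera from limma, with its preset correlation of 0.01, repeated with an estimated correlation and with fry. Each gene was represented by the probe set with the highest mean over all arrays. Lists needed 4 measured genes, which 28 reached, and p-values were adjusted over the lists of a comparison. Beside each list stands the number of its genes that passed, and in brackets the number that passed when adjusted over the list alone, where that differed. The lists, the tests, the floor, the filter, the thresholds and most alternatives were fixed before the data were examined.

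Genes were named by a fixed rule. For each comparison of extraocular muscle it took the 5 largest folds on each side among called genes whose arrays did not overlap and lay above the floor, and the 5 brightest genes on each side with the dimmer tissue at the floor. The other comparisons had 3 in place of 5. For the sets the 6 brightest genes were taken (10 for extraocular muscle), and for each list up to 4 called members with the largest folds. Some genes that the rule allowed are not named, but their folds were kept in the counts of how far the alternatives changed them. Folds were not repeated with other fold minimums, with a single probe set per gene or without suspected probe sets.

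A probe set was taken as suspected of saturation, by a rule chosen after seeing the data, when it read over 10000 on an array and more than 10 times lower on another of the same tissue, or at most 2 on any array and over 10000 on another. This held for 55 tested probe sets. A probe set that read low alike on every array of a tissue could escape the rule. Pairing by replicate number was checked by correlating the deviations of equally numbered arrays from their tissue means, which gave -0.075 to 0.327. For extraocular with cardiac muscle the values were 0.14, 0.327, 0.029 and 0.203 for numbers 1 to 4. Arrays of unequal number were not compared, so the check cannot exclude that the numbers pair arrays. The numbers were not used to pair arrays, and a replicate block was tried as an alternative.

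The calling was tested on simulated data, with the spread of each probe set pooled over the tissues. Each probe set was drawn independently, and the changed ones were taken from those with a mean well above the floor. Of probe sets changed 3-fold, 67 to 81% were recovered per pair of tissues, and of those changed 6-fold 92 to 98%, with 4 to 8 false calls among 7131 unchanged. For the sets these shares were 61 to 72% and 91 to 94%, with 0 false calls (limma, adjusted p, fold minimum). In the real data stomach arrays resembled each other less (mean correlation 0.869) than cardiac arrays did (0.946). The simulation does not show how many false calls a spread that differs between tissues would give. A list raised 2-fold was detected in 3 of 3 contrasts, with 0 of 78 tests of other lists called by camera or with an estimated correlation. Since the simulated genes were independent, this does not show how often lists of correlated genes are called falsely.

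Alternatives covered the normalization (quantile, trimmed mean, median), the floor at the 15th or 45th percentile or a pseudocount, the filter, the fold minimum, fits of only the tissues compared, array weights, an intensity trend with robust settings, a replicate block, a single probe set per gene, rank correlation for the arrays, the list tests, and leaving out each array in turn. After seeing the data, 2 more were added, leaving out probe sets suspected of saturation and leaving out extraocular muscle 4 and stomach smooth muscle 1 together. Other splits of the arrays were counted, up to 100 drawn with a fixed seed. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the annotation and the figures.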

Results

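Total RNA from 4 muscle tissues of control adult rats was measured on 14 oligonucleotide arrays of one design. Extraocular muscle, which moves the eye, and cardiac muscle had 4 arrays each. Leg muscle (gastrocnemius and soleus) and stomach smooth muscle (stomach wall after removal of the epithelium) had 3 arrays each. Between 63.8% and 78.9% of the probe sets of an array lay above the floor of 208.5 intensity units, and the number of arrays limits the precision of every value. Signed differences are log2 values of the first-named tissue minus the second, with the standard error of the fit, and folds against a tissue at the floor on every array are lower bounds. Where only some arrays of the dimmer tissue lay at the floor, the fold is given as measured and is a low estimate. The labels do not say whether the replicates are separate animals, so p-values measure only the spread between these samples.

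On average, arrays of one tissue resembled each other more than arrays of another tissue. The mean correlation between arrays, across 7331 probe sets, was 0.922 within extraocular muscle, 0.938 within leg muscle, 0.946 within cardiac muscle and 0.869 within stomach smooth muscle. Between tissues it was 0.895 for extraocular with leg muscle, 0.857 for extraocular with cardiac muscle, 0.848 for leg with cardiac muscle, and 0.688, 0.653 and 0.693 for stomach with extraocular, leg and cardiac muscle. Single pairs of extraocular and leg arrays reached 0.927, above the lowest pair within extraocular muscle (0.899). Probe sets are not independent replicates, so these values describe the arrays and carry no test. The mean within tissues exceeded the mean between tissues by 0.142. Stomach smooth muscle 1 stood apart from its group, with a mean correlation of 0.844 with the other stomach arrays, the most probe sets above the floor, and 31 probe sets at over 6 times their level on any other array.

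**Figure D1:**
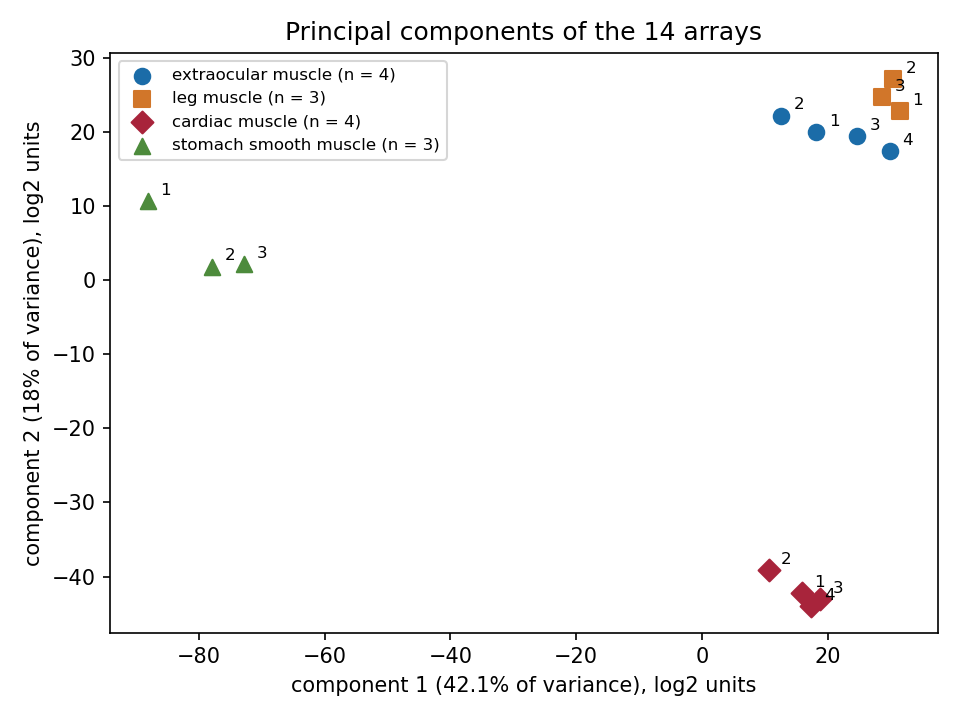
Principal components of the 14 arrays from log2 intensity, with component 1 (42.1% of variance) against component 2 (18% of variance), and numbers giving the replicate. The 3 stomach arrays lie apart on component 1 and the 4 cardiac arrays on component 2, while extraocular and leg arrays lie next to each other.

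A few signs of array and RNA quality differed between tissues. The log2 ratio of the 3' to the 5' hexokinase control was -0.34 to -0.21 on leg arrays, 1.06 to 2.39 on extraocular arrays, 0.89 to 1.42 on cardiac arrays and 1.25 to 3.52 on stomach arrays. The bioB 5' spike-in control read 83.2 to 126.6 on stomach arrays and 769.2 or more on every other array. The middle bioB control also separated them (130.6 to 392.4 against 573 or more). The bioB 3' and bioC 3' controls overlapped, at 93.6 to 345.5 and 367.6 to 1808.3 on stomach arrays and 50.1 and 1210 on extraocular muscle 1. Given the controls that separated stomach, tissue and array processing cannot be told apart in the comparisons with it. The hexokinase ratio set the leg arrays apart from every other array, so tissue and RNA quality cannot be told apart there. Some of the brightest muscle transcripts were suspected of saturation, by a rule chosen after the data were seen. On each leg array the probe sets for skeletal actin (Acta1), muscle aldolase (Aldoa) and the middle part of Gapdh read nearly the same value, 1050, 1051 and 1053 on leg muscle 1, far below the brightest probe set of that array at 41810. A total of 55 tested probe sets met that rule, and folds of the genes they represent are given with that remark. The rule can miss a probe set that read low alike on all arrays of a tissue, so folds without the remark are not cleared.

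**Figure D2:**
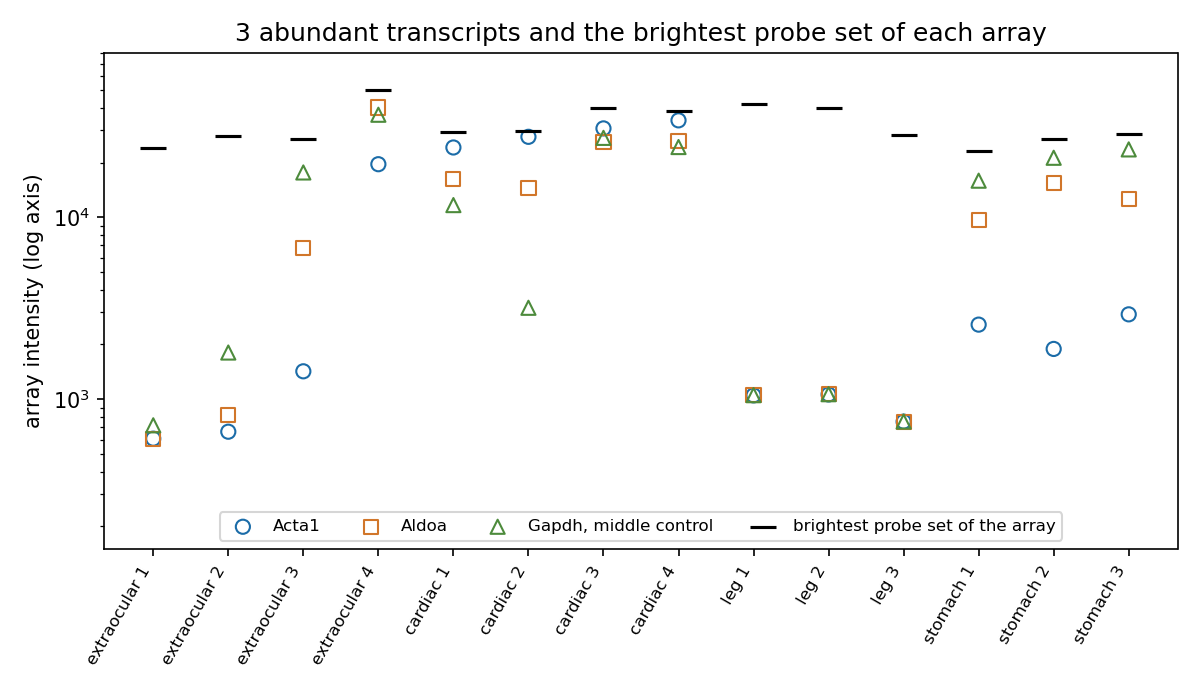
Intensity (log axis) of Acta1, Aldoa, the middle Gapdh control and the brightest probe set on each of the 14 arrays. The 3 transcripts coincide at about 1053, 1066 and 754 on the leg arrays and spread from 11671 to 24198 on cardiac muscle 1.

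Extraocular muscle against leg muscle asks how the muscles of the eye differ from a limb muscle of the same striated type. Extraocular muscle carried myosin heavy chains that leg muscle hardly showed. Myh13, the extraocular myosin, was 46.5-fold higher (5.54 ± 0.51, adjusted p = 3.34e-05) and reached 21400 intensity units, with 2 of 3 leg arrays above the floor. Myh8, the perinatal myosin, was at least 43.8-fold higher (5.45 ± 0.17, adjusted p = 1.40e-10), with every leg array at the floor. The lists for the nerve-muscle synapse, the matrix and nerve shifted higher in extraocular muscle with the preset correlation of the test, and did not pass with an estimated one.

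Among 7331 probe sets tested with n = 4 and n = 3, 299 differed, 206 higher and 93 lower in extraocular muscle (68.9% higher). They covered 158 genes higher and 64 lower. The adjusted p alone was met by 345. The count changed when single arrays were left out, falling to 176 without leg muscle 1 and to 168 without leg muscle 2. With n = 3, leaving out a leg array also lowers the power, so the fall need not reflect the values of those arrays. A fit of these 7 arrays alone gave 152.

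The largest folds higher in extraocular muscle, with all arrays above the floor, were for Stk39, a kinase that regulates chloride cotransporters, at 17.9-fold (4.16 ± 0.33, adjusted p = 7.93e-06, in 2 of its 3 probe sets) and Mgst1, a microsomal glutathione transferase, at 8.8-fold (3.14 ± 0.54, adjusted p = 0.00434). Scd, which desaturates fatty acids, was 7.77-fold higher (2.96 ± 0.61), Ptgds, a prostaglandin D synthase, 6.75-fold (2.75 ± 0.62), and the membrane protein gene Tmem47 5.87-fold (2.55 ± 0.28). With leg muscle at the floor, Sptan1 (non-erythroid spectrin) was at least 3.75-fold higher, Ezr (ezrin) at least 3.48-fold, Ptprf (a receptor tyrosine phosphatase) at least 3.42-fold and Ddc (dopa decarboxylase) at least 3.07-fold. Lower in extraocular muscle were Atp1b2, a sodium pump subunit (-2.74 ± 0.51, in 2 of 3 probe sets), Pdk4, which restrains pyruvate oxidation (-2.59 ± 0.56), the scaffold gene Homer2 (-2.28 ± 0.49), Ppp1r1a, a phosphatase inhibitor (-2.18 ± 0.36), and Pfkfb1, which sets fructose 2,6-bisphosphate (-2.18 ± 0.37, in 1 of its 4 probe sets). Comp, a matrix glycoprotein, was at the floor on every extraocular array and at least 2.05-fold lower. Without leg muscle 1 the calls of Ptgds, Sptan1, Ddc, Pdk4, Homer2 and Comp were lost (adjusted p 0.058 to 0.137). Without leg muscle 2 those of Scd, Ptgds, Sptan1, Ddc, Pdk4 and Comp were lost (0.0523 to 0.139), and without leg muscle 3 those of Scd, Ptgds and Ddc (0.052 to 0.0932). Leaving out extraocular muscle 1 ended Ptgds, Ddc and Comp (0.0527 to 0.064), extraocular muscle 2 Ptgds (0.0516), extraocular muscle 3 Ddc and Comp (0.0555 to 0.0925), and extraocular muscle 4 Ddc (0.0682). In a fit of the arrays of these tissues alone, 26 of the 58 folds considered for the text were not called, among them Mgst1, Ptgds, Sptan1, Ezr, Ddc, Pdk4, Pfkfb1 and Comp (0.0678 to 0.175).

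The neuromuscular junction list was higher as a group (camera adjusted p = 0.00456, adjusted p = 0.244 with an estimated correlation). Of its 16 measured genes 3 rose and 13 did not pass (4 rose adjusted over the list alone). These were the acetylcholine receptor subunits Chrna1 (1.43 ± 0.25), Chrne (1.4 ± 0.29) and Chrnd (1.2 ± 0.29). The extracellular matrix list had 3 of 26 genes higher (4 adjusted over the list alone), with camera adjusted p = 0.00456 and adjusted p = 0.286 with an estimated correlation. They were Lum, a collagen-binding proteoglycan (1.89 ± 0.35), Postn, periostin (1.36 ± 0.34), and Mmp2, a gelatinase (1.13 ± 0.26, in 1 of 2 probe sets). Of the nerve and Schwann cell list, 4 of 24 genes rose (7 adjusted over the list alone), among them the myelin genes Cnp (2.16 ± 0.33, 2 of 3 leg arrays above the floor) and Pmp22 (1.63 ± 0.3, in 1 of 2 probe sets). Its camera adjusted p was 0.043, and adjusted p = 0.286 with an estimated correlation. The antioxidant list (camera adjusted p = 0.0104, adjusted p = 0.286 with an estimated correlation) had 1 of 22 genes higher, the glutathione transferase Gstm2 (1.43 ± 0.29). Smooth muscle contractile genes had a median difference of 0.83, with 2 of 17 higher (4 adjusted over the list alone), Actg2 (2.09 ± 0.5, or 1.38 without leg muscle 1, 2 of 3 leg arrays above the floor) and Csrp1 (1.06 ± 0.24). Their camera adjusted p was 0.043, and adjusted p = 0.286 with an estimated correlation. The endothelium list, a marker of vessels, had a median of -0.14 and none of 13 genes passing.

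Single arrays and other settings ended some of these calls. Without extraocular muscle 4 the smooth muscle list had adjusted p = 0.185 and the nerve list 0.167, and the nerve list had 0.0513 without leg muscle 2 and 0.0934 without leg muscle 3. With the floor at the 15th percentile the neuromuscular junction list had adjusted p = 0.0728, the smooth muscle list 0.06 and the nerve list 0.106. With no filter the smooth muscle and nerve lists each had 0.0661, and with a replicate block they had 0.0807 and 0.0755. Without extraocular muscle 4 and stomach smooth muscle 1, an alternative chosen after the data were seen, they had 0.275 and 0.115. Without leg muscle 1, Chrnd, Chrne, Actg2, Csrp1, Mmp2, Postn and Gstm2 were no longer called (0.0635 to 0.125). The same held without leg muscle 2 for Chrnd, Csrp1, Mmp2 and Postn (0.11 to 0.185) and without leg muscle 3 for Chrnd (0.0623). Of the extraocular arrays, replicate 1 ended Chrnd, Actg2, Csrp1, Mmp2 and Postn (0.0531 to 0.0812), replicate 2 Actg2, Mmp2 and Postn (0.052 to 0.0696), replicate 3 Chrnd, Actg2 and Postn (0.0506 to 0.0893), and replicate 4 Postn (0.0569) and, through its fold, Csrp1.

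Fuel metabolism was mixed. In the glycolysis list 1 of 16 genes rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.799). Gpd1, glycerol phosphate dehydrogenase, was 13.2-fold lower in extraocular muscle (-3.72 ± 0.48, adjusted p = 5.61e-04, 3 of 4 extraocular arrays above the floor) and Pfkfb1 4.53-fold lower, while Hk1, hexokinase, was higher (1.32 ± 0.22, in 1 of 2 probe sets), beside the 3' to 5' hexokinase ratios that were lowest on leg arrays. Glycogen metabolism had 1 of 10 genes lower (2 adjusted over the list alone), the phosphorylase kinase subunit Phka1 (-1.9 ± 0.33), with camera adjusted p = 0.0848 for the list, 0.0346 without extraocular muscle 3 and 0.387 with an estimated correlation. Of 24 genes for fatty acid uptake and oxidation 2 rose, one of them Decr1, an auxiliary enzyme of oxidation (1.4 ± 0.32, in 1 of 2 probe sets, adjusted p = 0.101 without leg muscle 1, 0.124 without leg muscle 2 and 0.0591 without extraocular muscle 3). No gene of 30 in the TCA cycle and respiratory chain list passed (median -0.25, camera adjusted p = 0.0871). That list met the threshold at adjusted p = 1.24e-04 without extraocular muscle 4, at 0.0346 without extraocular muscle 3, at 0.0316 without leg muscle 3, at 0.00536 with a replicate block and at 3.19e-04 without extraocular muscle 4 and stomach smooth muscle 1. It had 0.767 with an estimated correlation.

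Some single genes of excitation, calcium handling and adenylate metabolism were lower in extraocular muscle, while their lists did not shift. Cacng1, a subunit of the muscle calcium channel (-2.09 ± 0.4), Ampd1, muscle AMP deaminase (-1.93 ± 0.34, in 1 of 2 probe sets), and Clcn1, the muscle chloride channel (-1.43 ± 0.27, 2 of 4 extraocular arrays above the floor), were among them. They belong to the calcium handling list (1 of 25 genes higher and 1 lower, median -0.11, camera adjusted p = 0.583), the creatine kinase and adenylate list (1 of 9 lower) and the ion pump and channel list (2 of 17 lower, median -0.05, camera adjusted p = 0.641). The fast sarcomere list had none of 11 genes passing (median -0.27) and the slow list none of 7 (median -0.64). The fast list met the threshold at adjusted p = 0.0208 without extraocular muscle 4 and 0.0437 without extraocular muscle 3, at 0.0258 without extraocular muscle 4 and stomach smooth muscle 1, and had 0.141 with all arrays and 0.539 with an estimated correlation. Of their probe sets, 3 and 1 were suspected of saturation. Of 26 cardiac-enriched genes 2 were lower. In the list of myogenic and cardiac transcription factors 2 of 12 genes rose (and 1 fell adjusted over the list alone), one of them Id1 (1.16 ± 0.22, in 1 of 2 probe sets), a helix-loop-helix inhibitor of differentiation factors. Of 17 developmental isoforms and factors 2 rose, Myh8 among them. Their median was -0.06, with a mean of 0.02. The list of genes associated with extraocular muscle had 2 of 11 genes higher and 2 lower (2 and 3 adjusted over the list alone), with a median of -0.11 and a mean of 0.38. Embryonic myosin (Myh3) was represented by 5 probe sets that disagreed. The one with the highest mean showed saturation signs (-2.99 ± 1.10, adjusted p = 0.162), another lay near the floor (0.21 ± 0.27), and 3 were higher in extraocular muscle (4.64 ± 0.34, 3.44 ± 0.39 and 2.76 ± 0.27). They were singled out after their values were seen.

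The remaining lists held few changes between extraocular and leg muscle. Early response and stress genes had 1 of 18 higher and 2 lower (1 and 3 adjusted over the list alone), with Nr4a1 (-1.44 ± 0.27) and Jun (-1.13 ± 0.18, in 2 of 4 probe sets), both induced early after stimuli, lower in extraocular muscle. Adipose genes had 2 of 14 higher, Scd one of them, and 1 lower, Gpd1. Their median was -0.04 and their mean 0.07. Exocrine gland genes had 1 of 13 higher, the kallikrein Klk1 (2.07 ± 0.44, in 1 of 2 probe sets, adjusted p = 0.0541 without leg muscle 1). The gastric epithelium list had 1 of 17 genes higher. No gene passed in the lists for the dystrophin complex (7 genes), blood cells (6), immune cells (22), mast cells (9) and keratinised epithelium (7). In the fit of the extraocular and leg arrays alone, Pmp22, Actg2, Csrp1, Postn, Lum, Gstm2, Decr1, Klk1, Gpd1 and Clcn1 were not called (0.0552 to 0.119).

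Other settings ended further calls of genes named for these tissues, with the adjusted p in brackets. The floor at the 15th percentile ended Chrnd (0.224), Chrne (0.174), Actg2 (0.123), Comp (0.0976), Cacng1 (0.0951), Phka1 (0.0776), Klk1 (0.0619) and Postn (0.0596). The floor at the 45th ended Ddc (0.38), Ezr (0.185), Sptan1 (0.135) and Ptprf (0.0787). Median scaling ended Csrp1 (0.105), Decr1 (0.0962), Ddc (0.0945), Mmp2 (0.0715), Postn (0.0589), Homer2 (0.0538), Actg2 (0.0503) and, through its fold, Comp. With no filter Ddc (0.0851), Actg2 (0.0633), Postn (0.0582) and Ptgds (0.0536) were not called, and with a pseudocount Comp (0.104), Chrnd (0.054) and, through its fold, Csrp1. A replicate block ended Ddc (0.0896), Postn (0.0659) and Csrp1 (0.0507), and quantile normalization Ddc (0.0839) and, through its fold, Comp. Without extraocular muscle 4 and stomach smooth muscle 1, Ddc (0.0638), Postn (0.0543) and, through its fold, Csrp1 were not called.

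**Figure D3:**
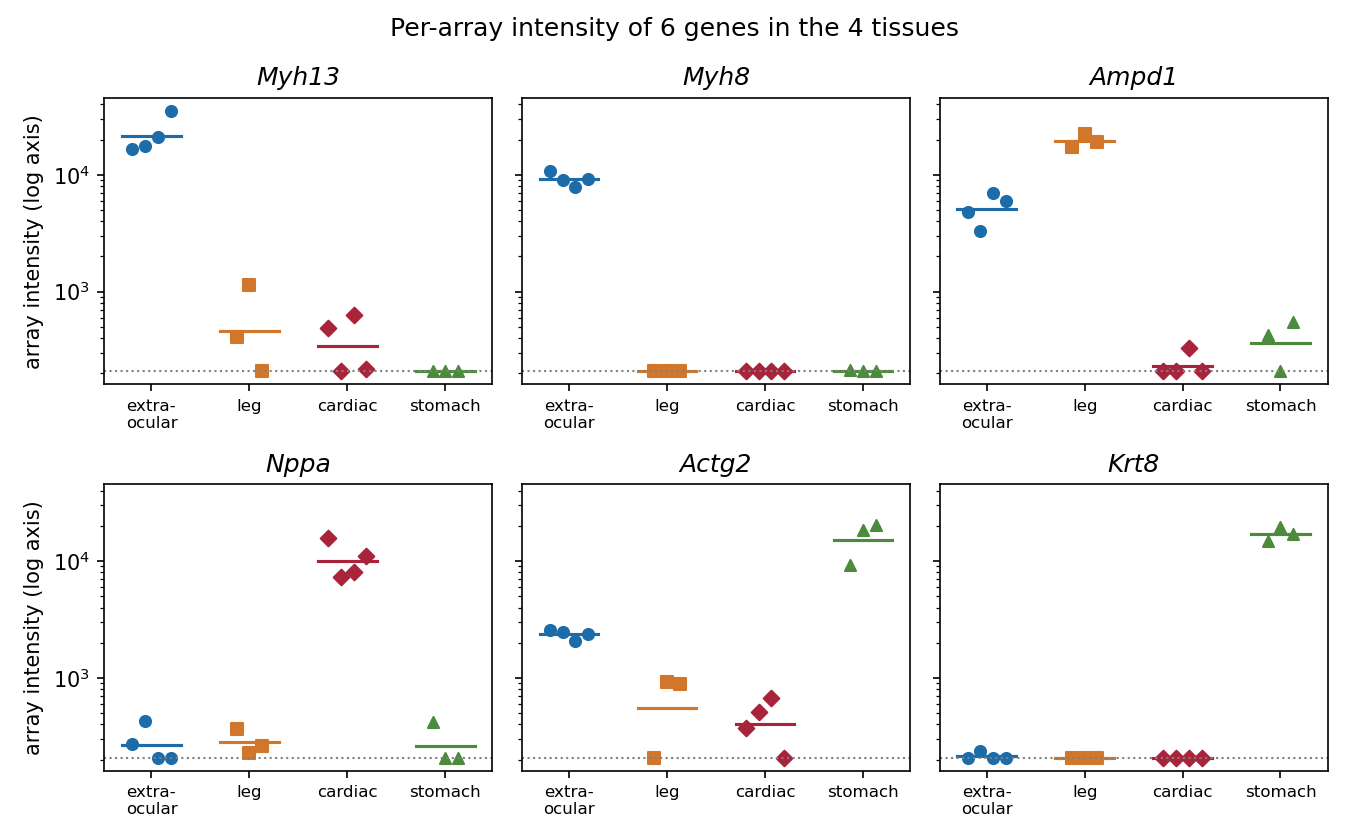
Intensity (log axis) of 6 genes on each array, with bars at the geometric mean and a dotted line at the floor of 208.5. Myh13 and Myh8 are high on the 4 extraocular arrays, Ampd1 on leg arrays, Nppa on cardiac arrays and Krt8 on the 3 stomach arrays, while Actg2 has a geometric mean of 15100 in stomach and 2360 in extraocular muscle.

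Extraocular muscle against cardiac muscle sets a skeletal muscle against the other striated type. Extraocular muscle had the fast sarcomere genes that cardiac muscle lacked or nearly lacked, led by Tnni2, fast troponin I, at least 118-fold higher (6.88 ± 0.2, adjusted p = 1.40e-11), and Myh2, a fast myosin, at least 90.6-fold (6.5 ± 0.2). Cardiac muscle had its own troponin and natriuretic peptide genes and a higher list of fat oxidation genes. Tnni3, cardiac troponin I, was at least 74.7-fold lower in extraocular muscle (-6.22 ± 0.36, adjusted p = 2.19e-08, in 1 of 2 probe sets). Pln, phospholamban, the inhibitor of the calcium pump, was 49.3-fold lower (-5.62 ± 0.29).

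With n = 4 in each tissue, 569 probe sets differed, 325 higher and 244 lower in extraocular muscle (57.1% higher). The adjusted p alone was met by 701. They covered 223 genes higher and 168 lower.

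In the fast sarcomere list 8 of 11 genes were higher in extraocular muscle and 1 lower (2 lower adjusted over the list alone), with a median of 5.24 (camera adjusted p = 7.02e-14). Besides Tnni2 and Myh2 these were Tnnc2 (46.1-fold, 5.53 ± 0.56), Myl1 (37.9-fold, 5.24 ± 0.24), Tnnt3 (18.3-fold, 4.19 ± 0.54), Mybpc2 (5.95 ± 0.27, 2 of 4 cardiac arrays above the floor), Myh4 (5.84 ± 0.38, 3 of 4) and Neb (4.94 ± 0.31, 1 of 4, with signs of saturation). The gene lower was Acta1 (-3.98 ± 0.79), whose probe set read between 607 and 1424 on extraocular arrays 1 to 3 and 19581 on extraocular muscle 4, with signs of saturation. Slow sarcomere genes had 3 of 7 higher, Mybpc1 (5.99 ± 0.31), Tnni1, slow troponin I (3.84 ± 0.36), and Myl2 (2.11 ± 0.44). That list's adjusted p was 4.07e-04, and adjusted p = 0.0869 with an estimated correlation.

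Of the cardiac-enriched list 11 of 26 genes were lower in extraocular muscle and none higher (camera adjusted p = 8.05e-13). Examples are Nppb (-5.69 ± 0.31) and Nppa (-5.24 ± 0.33), the natriuretic peptides, with 1 and 2 of 4 extraocular arrays above the floor, and Ryr2, the cardiac calcium release channel (-2.61 ± 0.34). Large folds lower with all arrays above the floor were also seen for Ankrd1, a cardiac ankyrin repeat protein (34.4-fold, -5.11 ± 0.35), the LIM gene Fhl2 (31.2-fold, -4.96 ± 0.54) and the small GTPase gene Rrad (16.8-fold, -4.07 ± 0.22). Spink8 (at least 34.3-fold), Gnb3, a G protein subunit (at least 5.09-fold), and Pla2g5, a phospholipase (at least 3.86-fold), were at the floor on every extraocular array. So was Adarb1 (at least 2.98-fold, -1.57 ± 0.47, adjusted p = 0.0495), an RNA editing enzyme. The call of Adarb1 was lost without extraocular muscle 1, 2, 3 or 4 or cardiac muscle 1, 3 or 4 (adjusted p 0.0866 to 0.157). In a fit of the arrays of these tissues alone, Adarb1 (0.0895), Acta1 (0.0591) and S100b (0.0583) were not called. Adarb1 was also not called with the floor at the 45th percentile (0.105), with no filter (0.102) or with a replicate block (0.0504), and with that floor the fold of Pla2g5 fell short. In the transcription factor list 3 of 12 genes were higher, among them the myogenic factors Myf6 (4.89 ± 0.31, 1 of 4 cardiac arrays above the floor) and Myod1 (at least 7.87-fold, 2.98 ± 0.44), and 2 were lower, Ankrd1 and Nkx2-5, a cardiac homeobox gene (-2.16 ± 0.48).

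In the neuromuscular junction list 7 of 16 genes were higher and none lower (camera adjusted p = 4.07e-04, 0.0339 with an estimated correlation), among them Chrne (3.8 ± 0.27), Chrna1 (3.17 ± 0.23), Scn4a, the muscle sodium channel (2.88 ± 0.31, in 1 of 3 probe sets), and Chrnb1 (2.45 ± 0.3). Developmental isoforms and factors had 6 of 17 higher (7 adjusted over the list alone, camera adjusted p = 3.44e-05, 0.00608 with an estimated correlation), with Myh8 at least 43.8-fold higher, the imprinted RNA H19 (3.33 ± 0.22) and Dlk1 (1.89 ± 0.3). Extraocular-associated genes had 2 of 11 higher, Myh13 (62.1-fold, 5.96 ± 0.48) and Myh8. Their median was -0.17 and their mean 0.72. The fatty acid list had 3 of 24 genes lower in extraocular muscle (5 adjusted over the list alone, camera adjusted p = 2.23e-05, 0.00608 with an estimated correlation), Cpt1a, which commits fatty acids to mitochondria (-1.55 ± 0.31), Lpl, lipoprotein lipase (-1.28 ± 0.2), and Eci1 (-1.18 ± 0.26, in 1 of 4 probe sets). The TCA cycle and respiratory list had a median of -0.29 with no gene of 30 passing (camera adjusted p = 0.00455, and adjusted p = 0.59 with an estimated correlation). Its adjusted p was 0.0963 without extraocular muscle 1 and 0.117 without extraocular muscle 2.

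Calcium handling genes went both ways, 5 of 25 higher and 5 lower (7 and 5 adjusted over the list alone). Pvalb, the calcium buffer parvalbumin, was 37.7-fold higher (5.24 ± 0.48) and Cacna1s, the skeletal calcium channel, at least 26.9-fold (4.75 ± 0.21). Glycolysis had 3 of 16 genes higher and 1 lower (3 and 2 adjusted over the list alone), with Eno3, muscle enolase (2.31 ± 0.19), and Aldoc (2.69 ± 0.52, 1 of 4 cardiac arrays above the floor) higher. Of 10 glycogen genes 2 were higher and 1 lower, Pygb, brain-type phosphorylase (-2.71 ± 0.26). That list had camera adjusted p = 0.0702, 0.0373 with no filter, 0.0405 without cardiac muscle 2 and 0.298 with an estimated correlation. Early response and stress genes had 2 of 18 higher (camera adjusted p = 0.0677, 0.0476 with median scaling, 0.0326 with no filter and 0.184 with an estimated correlation). Ampd1 was 21.8-fold higher (4.44 ± 0.31, 1 of 4 cardiac arrays above the floor).

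Smooth muscle genes had 5 of 17 higher in extraocular than in cardiac muscle (6 adjusted over the list alone, camera adjusted p = 0.00249, and adjusted p = 0.0827 with an estimated correlation), such as Tpm2 (3.57 ± 0.46), Actg2 (2.55 ± 0.46) and Tagln (1.71 ± 0.28). Matrix genes had 5 of 26 higher and 1 lower (6 and 1 adjusted over the list alone), with Postn (3.6 ± 0.32) and Fn1, fibronectin (1.7 ± 0.25, in 1 of 3 probe sets). The matrix list had camera adjusted p = 0.012, and adjusted p = 0.238 with an estimated correlation. The nerve list had 6 of 24 higher (camera adjusted p = 0.0368, and adjusted p = 0.184 with an estimated correlation), with the myelin gene Mbp (2.98 ± 0.46, 1 of 4 cardiac arrays above the floor) and S100b (at least 5.18-fold, in 1 of 2 probe sets). Without extraocular muscle 4 the matrix list had adjusted p = 0.0745 and the nerve list 0.102, and without cardiac muscle 1 the nerve list had 0.0679. With the floor at the 15th percentile the nerve list had 0.0918, and without extraocular muscle 4 and stomach smooth muscle 1 the matrix list had 0.0948 and the nerve list 0.0847. The adipose list had 3 of 14 genes higher (4 adjusted over the list alone, median 0.14, camera adjusted p = 0.722), among them Scd (22.3-fold, 4.48 ± 0.57) and Cfd, adipsin (2.66 ± 0.52). The exocrine gland list had 2 of 13 higher (median 0.2, camera adjusted p = 0.135), Klk1 (3.53 ± 0.41) and Cpa1, a carboxypeptidase (at least 6.14-fold). Cxcl14, a chemokine, was at least 18.6-fold higher. No list of endothelial, blood, gastric or keratinised cells had a gene lower, and the gastric list had 1 of 17 higher. The immune list had 1 of 22 lower, Cd74 (-1.36 ± 0.32), the invariant chain.

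Extraocular muscle against stomach smooth muscle gave far more differences, on stomach arrays whose bioB 5' control also read lower. Striated muscle genes were high in extraocular muscle and at or near the floor in stomach, such as Pygm, muscle phosphorylase (78.7-fold, 6.3 ± 0.24, adjusted p = 1.70e-10), and Cox8b, a respiratory subunit (at least 113-fold, 6.83 ± 0.29). Stomach arrays had more of some smooth muscle genes, though that list did not pass, and more of epithelial and gland genes such as Chia, a gastric chitinase (at least 93.3-fold lower in extraocular muscle, -6.54 ± 0.17, adjusted p = 8.52e-12), and Krt18, an epithelial keratin (44.2-fold lower, -5.47 ± 0.33). The labels state that the epithelium was removed from the stomach wall.

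With n = 4 and n = 3, 1757 probe sets differed, 790 higher and 967 lower in extraocular muscle (45% higher). They covered 557 genes higher and 655 lower, and the adjusted p alone was met by 2241. Scaling each array to the same median moved the share higher to 56.8%, with 991 higher and 755 lower, and the median of all probe sets from -0.10 to 0.07. Quantile normalization gave 51.6% higher. Without stomach smooth muscle 1, 800 were higher and 782 lower (50.6%), and without this array and extraocular muscle 4 the share was 53.1%. The balance of the directions thus depended on the scaling and on which arrays were kept.

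Fast sarcomere genes had 8 of 11 higher (camera adjusted p = 2.32e-09, 0.00585 with an estimated correlation), with Tnni2 (108-fold, 1 of 3 stomach arrays above the floor), Myh2 (71.4-fold) and Myh4 (45-fold). The slow list had 6 of 7 higher and 1 lower (camera adjusted p = 1.34e-04, and adjusted p = 0.0692 with an estimated correlation), with Mybpc1 (63.9-fold) and Myl2 (41.1-fold). Myh13 was at least 103-fold higher, Myh8 43.4-fold with 1 of 3 stomach arrays above the floor, Klhl41, a sarcomere-associated kelch protein, at least 43.7-fold, Eef1a2, a muscle elongation factor, at least 54.7-fold, and Neb, nebulin, at least 34.1-fold with signs of saturation. The extraocular-associated list had 3 of 11 higher (camera adjusted p = 0.00645, and adjusted p = 0.0961 with an estimated correlation). Developmental genes had 6 of 17 higher (camera adjusted p = 2.29e-05, 0.00585 with an estimated correlation), among them H19 (25-fold), Igf2, a growth factor (6.28-fold, in 1 of 5 probe sets), and Igfbp5 (6.1-fold, in 1 of 2 probe sets).

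Of the fuel lists, that of fatty acid genes was higher in extraocular muscle than in stomach with either correlation, and those of glycolysis, glycogen and the TCA cycle only with the preset one. The fatty acid list had 12 of 24 higher and 1 lower (12 and 2 adjusted over the list alone, camera adjusted p = 5.96e-06, 0.00585 with an estimated correlation), with Cpt1b, the muscle carnitine transferase (5.1-fold), and Cd36, a fatty acid transporter (4.83-fold), while the liver-type Cpt1a was 4.79-fold lower. Glycolysis had 7 of 16 higher and 1 lower, with Eno3 (91.9-fold, 1 of 3 stomach arrays above the floor) and Pgam2 (19.9-fold). That list had camera adjusted p = 0.00645, adjusted p = 0.121 with an estimated correlation, and 0.0862 without extraocular muscle 4. Glycogen genes had 6 of 10 higher and 2 lower (6 and 3 adjusted over the list alone, camera adjusted p = 0.00348, and adjusted p = 0.0791 with an estimated correlation). The TCA and respiratory list had 4 of 30 higher (camera adjusted p = 7.88e-05, and adjusted p = 0.232 with an estimated correlation), with Cox8b, Cox6c (9.4-fold, in 1 of 2 probe sets) and Cox6a2 (37.9-fold, in 1 of 2 probe sets, with signs of saturation). In the creatine kinase list 2 of 9 were higher and 3 lower, with the muscle form Ckmt2 73.5-fold higher (1 of 3 stomach arrays above the floor) and the ubiquitous form Ckmt1 19.8-fold lower.

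Neuromuscular junction genes had 8 of 16 higher (camera adjusted p = 1.34e-04, 0.0317 with an estimated correlation), among them Chrna1 (16.9-fold) and Chrnb1 (9.82-fold), each with 2 of 3 stomach arrays above the floor. Calcium handling had 10 of 25 higher and 2 lower (camera adjusted p = 0.00645, and adjusted p = 0.108 with an estimated correlation). The dystrophin list had 2 of 7 higher (camera adjusted p = 0.0152, and adjusted p = 0.0791 with an estimated correlation), and ion pumps and channels had 4 of 17 higher and 1 lower (camera adjusted p = 0.0286, and adjusted p = 0.0791 with an estimated correlation). The ion list lost its call without extraocular muscle 2 (0.0565) or stomach smooth muscle 1 (0.0659), with quantile normalization (0.0688) and with median scaling (0.0568). Matrix genes had 9 of 26 higher and 1 lower (camera adjusted p = 0.00265, and adjusted p = 0.108 with an estimated correlation), with Mmp2 (3.62-fold, in 1 of 2 probe sets) and Col5a1 (3.6-fold). Stress genes had 7 of 18 higher and 1 lower (camera adjusted p = 0.00645, and adjusted p = 0.0692 with an estimated correlation), with the small heat shock genes Hspb1 (21.1-fold, in 2 of 4 probe sets) and Cryab (20.9-fold). Adipose genes had 5 of 14 higher (camera adjusted p = 0.0201, and adjusted p = 0.184 with an estimated correlation), a call lost without stomach smooth muscle 1 (0.0952) or extraocular muscle 2 (0.0729) and with median scaling (0.0568). Without extraocular muscle 4 and stomach smooth muscle 1 together, the extraocular-associated (0.178), glycolysis (0.206), dystrophin (0.0551), ion (0.129) and adipose (0.14) lists were not called. Of the endothelium list 3 of 13 were higher and 1 lower, with the water channel Aqp1 (9.48-fold) and Cav1, caveolin (8.95-fold).

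Lower in extraocular muscle were 5 of 17 smooth muscle genes, and 1 was higher (median -0.46, camera adjusted p = 0.0713). Cnn1, calponin, was 9.3-fold lower, Actg2 6.4-fold, Tagln 5.26-fold and Myh11, smooth muscle myosin, 4.36-fold. Without extraocular muscle 4 the list's adjusted p was 0.0403, without stomach smooth muscle 1 it was 0.032, without both 0.0193 and without probe sets suspected of saturation 0.0234. It was 0.259 without stomach smooth muscle 3 and 0.219 with an estimated correlation. The gastric epithelium list had 13 of 17 genes higher in stomach and 1 lower, with a median of -4.44 (camera adjusted p = 1.27e-08, and adjusted p = 0.0692 with an estimated correlation). Krt8 (-6.31 ± 0.17) and Sst, somatostatin (-6.14 ± 0.18), each with 1 of 4 extraocular arrays above the floor, Cblif, the vitamin B12 carrier of the stomach (-5.82 ± 0.32), and Atp4b, a subunit of the acid pump (-5.77 ± 0.25), were among the 13. The member with the opposite sign was Atp4a, the other pump subunit, whose brightest probe set gave 1.02 ± 0.30 while its other probe sets gave -5.02 ± 0.34 and -4.76 ± 0.24. It was singled out after its values were seen. Krt19 (35.8-fold), Ezr (19.2-fold), Hsd17b3 (34.4-fold), Lgals4 (at least 30.5-fold), Slc5a5, the iodide transporter (at least 31.7-fold), and Hdc, histidine decarboxylase (at least 40.7-fold), were also higher in stomach. Of the antioxidant list 3 of 22 were higher in extraocular muscle and 5 lower, Nqo1 (6.48-fold) and Gsta1 (4.29-fold) among the latter. Mast cell genes had 1 of 9 higher and 3 lower (median 0.05, mean -0.63), keratinised epithelium 2 of 7 lower, exocrine glands 2 of 13 higher and 5 lower, and the nerve list 6 of 24 higher and 3 lower (median -0.02, mean 0.13).

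**Figure D4:**
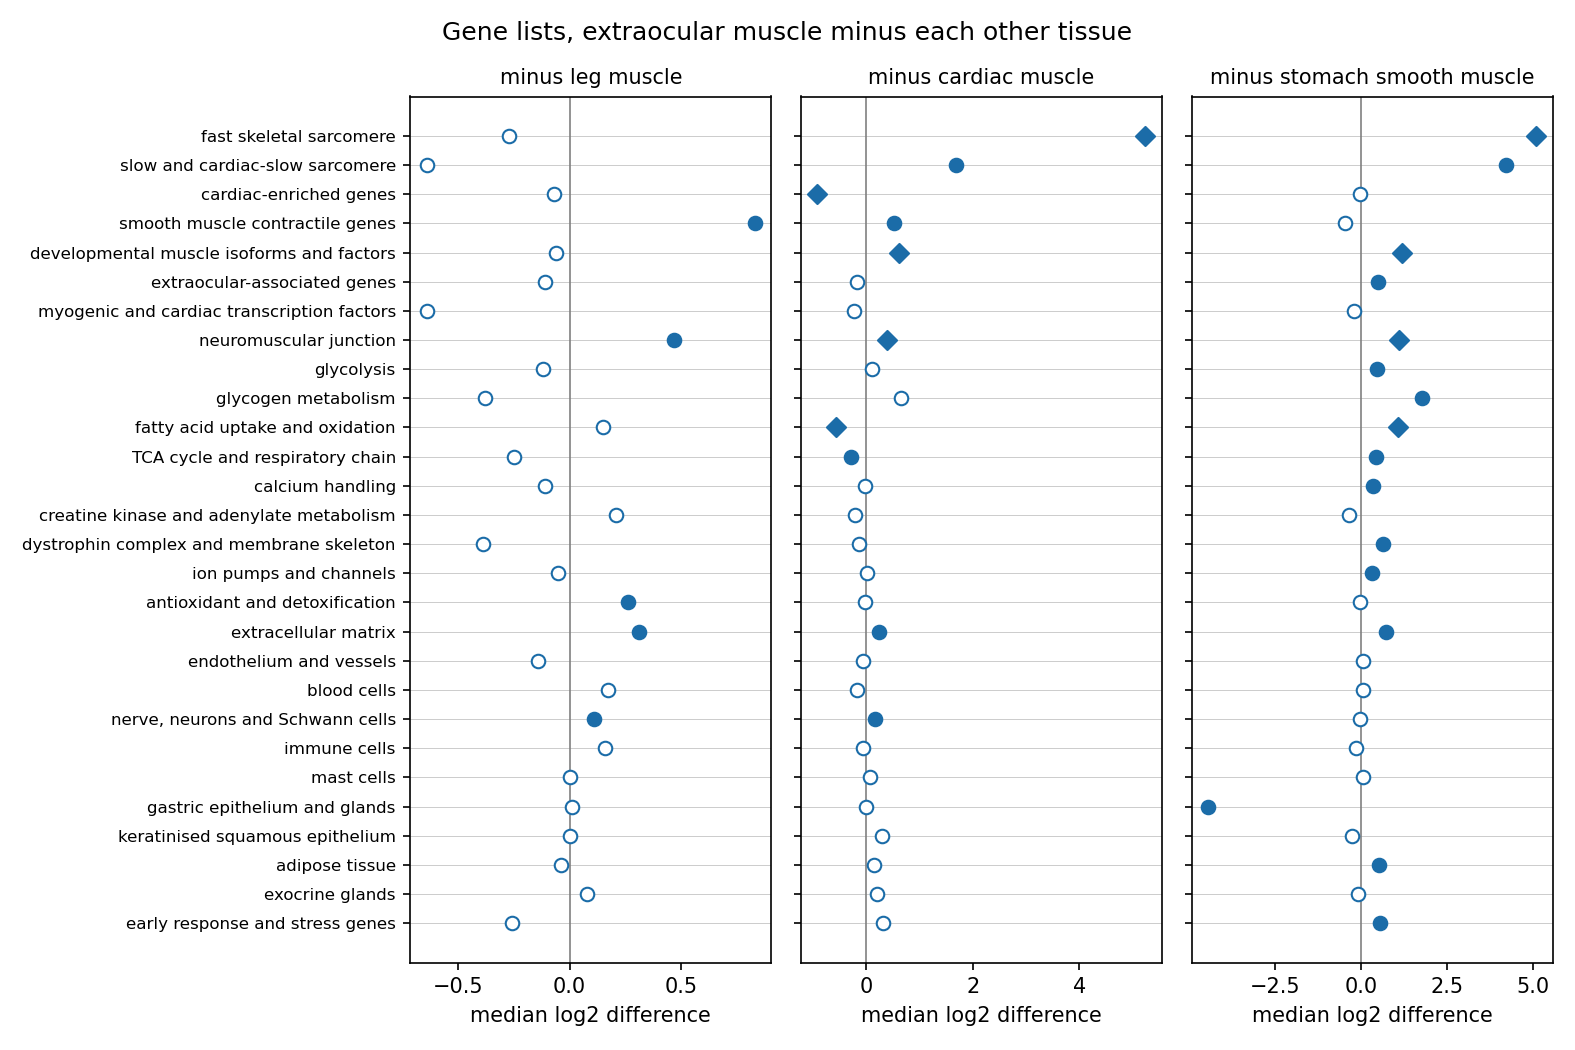
Median log2 difference of the genes of each fixed list, extraocular muscle minus leg, cardiac and stomach smooth muscle, filled where camera passed with its preset correlation and as a diamond where it also passed with an estimated one. The fast sarcomere list stands at 5.24 against cardiac muscle, 5.09 against stomach and -0.27 against leg muscle.

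Leg muscle against cardiac muscle gave 691 probe sets, 308 higher and 383 lower in leg muscle (44.6% higher), and 846 by the adjusted p alone. Tnni2 was higher by at least 7.15 ± 0.22 log2 units (adjusted p = 2.81e-11), Myh2 at least 129-fold and Cacna1s at least 46.6-fold. Myl1 (44.1-fold), Pvalb (40.8-fold) and Tnnc2 (39.4-fold) were higher with all arrays above the floor. Cardiac muscle had more Pln (93.3-fold, 1 of 3 leg arrays above the floor), Nppa (35.8-fold, -5.16 ± 0.35) and, with leg muscle at the floor, Tesc, tescalcin (at least 76.5-fold), Spink8 (at least 34.3-fold) and Ezr (at least 11.3-fold). Acta1 (-4.94 ± 0.86) and Aldoa (-4.41 ± 1.03) also read lower in leg muscle, both with signs of saturation on the leg arrays. Fast sarcomere genes had 8 of 11 higher and 1 lower (camera adjusted p = 1.74e-13, 0.00431 with an estimated correlation), cardiac-enriched genes 2 of 26 higher and 10 lower (2 and 12 adjusted over the list alone, camera adjusted p = 4.32e-08, 0.0374 with an estimated correlation), and fatty acid genes 1 of 24 higher and 6 lower (1 and 7 adjusted over the list alone, camera adjusted p = 5.32e-06, 0.00796 with an estimated correlation). Decr1 (-1.58 ± 0.32), Acadvl (-1.42 ± 0.27) and Cpt1a (-1.7 ± 0.34) were lower in leg muscle. Glycogen genes had 6 of 10 higher and 1 lower (camera adjusted p = 0.00931, and adjusted p = 0.144 with an estimated correlation), with Phka1 (11.3-fold, 2 of 4 cardiac arrays above the floor) higher and Pygb (8.72-fold) lower in leg muscle. Gpd1 (16.7-fold), Pfkfb1 (15.9-fold, in 2 of 4 probe sets) and Ampd1 (83.1-fold, 1 of 4 cardiac arrays above the floor) were higher in leg muscle. Also higher in leg muscle were the lists of slow sarcomere genes (3 of 7, 4 adjusted over the list alone, camera adjusted p = 6.98e-04, 0.105 with an estimated correlation), developmental isoforms (6 of 17, and 1 lower adjusted over the list alone, 0.00931 and 0.0524) and early response and stress genes (4 of 18, median 0.54, 0.00931 and 0.0853). The lists called were 7 of 28, and 3 held with an estimated correlation.

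Leg muscle against stomach smooth muscle gave 1941 probe sets, 840 higher and 1101 lower in leg muscle (43.3% higher), and 2322 by the adjusted p alone. Median scaling moved the median of all probe sets from -0.07 to 0.07 and the share higher to 52.7%. Pygm (104-fold, 6.7 ± 0.26, adjusted p = 2.15e-10), Myh2 (101-fold) and Mybpc1 (99.9-fold) were higher with all arrays above the floor, and Cox8b (at least 145-fold), Eef1a2 (at least 101-fold) and Neb (at least 62.7-fold, with signs of saturation) with stomach at the floor. Higher in stomach were Sult1c3, a sulfotransferase (39.6-fold), Muc5ac, a gastric mucin (29.5-fold), and Epcam, an epithelial adhesion molecule (25.3-fold), and with leg muscle at the floor Chia (at least 93.3-fold), Krt8 (at least 81.8-fold) and Sst (at least 76.7-fold). Smooth muscle genes had 8 of 17 higher in stomach and 1 lower (camera adjusted p = 0.0132, and adjusted p = 0.112 with an estimated correlation), with Actg2 (27.3-fold, 2 of 3 leg arrays above the floor), Cnn1 (21.2-fold), Myh11 (13.2-fold, in 1 of 2 probe sets) and Tagln (-3.39 ± 0.33). Fatty acid genes had 13 of 24 higher in leg muscle and 2 lower (13 and 3 adjusted over the list alone, camera adjusted p = 7.65e-05, 0.0191 with an estimated correlation), with Cpt1b (6.1-fold) and Cd36 (4.34-fold). The lists called were 16 of 28, and 3 held with an estimated correlation, those of fast sarcomere, developmental and fatty acid genes. Besides these and the smooth muscle list, 11 were higher in leg muscle, for slow sarcomere, extraocular-associated, synaptic, glycolysis, glycogen, TCA cycle, calcium, dystrophin, ion channel, adipose and stress genes (camera adjusted p 4.76e-06 to 0.0472, 0.0556 to 0.226 with an estimated correlation), and the gastric list was lower (3.71e-08 and 0.0586).

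Cardiac muscle against stomach smooth muscle gave 1892 probe sets, 829 higher and 1063 lower in cardiac muscle (43.8% higher), and 2368 by the adjusted p alone. With median scaling 1045 were higher and 799 lower (56.7% higher), and the median of all probe sets moved from -0.10 to 0.07. The share was 52.4% with quantile normalization, and without stomach smooth muscle 1 it was 50.6%, with 852 higher and 832 lower. Csrp3, muscle LIM protein, was 55.3-fold higher (5.79 ± 0.36, adjusted p = 2.35e-08), Pygm 51.8-fold, and Cox6a2 63.3-fold in 1 of 2 probe sets and with signs of saturation. With stomach at the floor, Cox8b was at least 117-fold higher, Eef1a2 at least 74-fold and Vegfb, a vascular growth factor, at least 9.68-fold. Krt18 (38.5-fold), Muc5ac (31.4-fold), Hsd17b3 (27.9-fold) and, with cardiac muscle at the floor, Krt8 (at least 81.8-fold), Atp4b (at least 54.6-fold) and Hdc (at least 40.7-fold) were higher in stomach. Cardiac-enriched genes had 12 of 26 higher and 1 lower (13 and 1 adjusted over the list alone, camera adjusted p = 1.57e-07, and adjusted p = 0.0795 with an estimated correlation), with Tnni3, Nppb and Nppa at 53.9-, 38.9- and 38.3-fold, each with 1 of 3 stomach arrays above the floor. Fatty acid genes had 15 of 24 higher and none lower (camera adjusted p = 3.94e-10, 0.00148 with an estimated correlation), with Cpt1b (8.62-fold), Cd36 (8.75-fold) and Acadl, a long-chain dehydrogenase (6.28-fold, in 1 of 2 probe sets). Smooth muscle genes had 10 of 17 higher in stomach and 1 lower (camera adjusted p = 0.00718, and adjusted p = 0.142 with an estimated correlation), with Actg2 (37.4-fold), Cnn1 (29.6-fold, 2 of 4 cardiac arrays above the floor), Tagln (17.2-fold) and Tpm2 (14.4-fold). The lists called were 10 of 28, and 1 held with an estimated correlation. Higher in cardiac muscle were also the extraocular-associated, glycolysis, glycogen, TCA cycle, calcium and dystrophin lists (camera adjusted p 2.54e-08 to 0.037, 0.142 to 0.2 with an estimated correlation), and the gastric list was lower (1.32e-08 and 0.142).

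Genes higher in one tissue than in each of the other 3 describe what sets that tissue apart. In extraocular muscle these were 28 probe sets of 17 genes. The brightest were Myh13, Pmp22, Myh8, Adcy2, an adenylyl cyclase, Igf1, a growth factor, Chrna1, Fbln5, an elastic fibre protein, Prx, periaxin of the nerve sheath, Fst, the myostatin antagonist follistatin, and Map2, a microtubule protein. Against leg muscle, the nearest tissue, Map2 was 5.05-fold higher (2.34 ± 0.31, 2 of 3 leg arrays above the floor, in 1 of 2 probe sets), Fst 4.68-fold (2.23 ± 0.35, 2 of 3 leg arrays above the floor), Igf1 3.58-fold (1.84 ± 0.24, in 1 of its 5 probe sets), Prx 2.96-fold (1.57 ± 0.27), Fbln5 2.89-fold (1.53 ± 0.26) and Adcy2 2.6-fold (1.38 ± 0.23). The count fell to 14 without leg muscle 1, 15 without leg muscle 2, 18 without extraocular muscle 1 and 17 without extraocular muscle 3. Fits of the tissues in pairs gave 6.

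Leg muscle had 21 such probe sets of 17 genes, led by Ampd1, Cacng1, Ppp1r1a, Car3, muscle carbonic anhydrase, Nr4a1 and Dnajb5, a chaperone partner. Against extraocular muscle Car3 was 4.07-fold higher and Dnajb5 2.23-fold. Against cardiac muscle Cacng1 was 23.2-fold higher, Car3 13.5-fold, Ppp1r1a 11.6-fold and Nr4a1 by 3.4 ± 0.27 log2 units. This count was the least stable, at 3 without leg muscle 2, 10 without leg muscle 1, 9 without extraocular muscle 1 and 8 without extraocular muscle 2. Fits of the tissues in pairs gave 0 by limma at an adjusted p, and 72 at an unadjusted p. Cardiac muscle had 78 probe sets of 56 genes, with Ankrd1, Pln, Fhl2, Rbpms, an RNA-binding protein, Eci1 and Tesc the brightest. Ankrd1 was 14.1-fold higher than in leg muscle and 62.7-fold higher than in stomach (2 of 3 stomach arrays above the floor), and Tesc 3.61-fold higher than in stomach. Stomach had 552 probe sets of 385 genes, with P4hb, protein disulfide isomerase, Chia, Cd24, Calm2, calmodulin, Tspan8 and Cblif the brightest. Against cardiac muscle, the lowest fold of these was 2.25 for P4hb (below the minimum with median scaling) and the next 3.68 for Calm2, while Cd24 (1 of 4 cardiac arrays above the floor) and Cblif (2 of 4) were 75.8-fold and 60.5-fold higher and Tspan8 18.1-fold.

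Over the 6 comparisons and 28 lists, camera called 64 of 168 list tests, and 16 of them held with an estimated correlation. A drawn regrouping of the arrays gave as many as 51 calls with the preset correlation, so that correlation alone gives limited evidence for a list. The fry test of a list's own direction, which does not compare it with other genes, called 101.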

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

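The search for arrays far from their group and the counts of other splits of the arrays were planned, while the tests of the abundant transcripts, the smooth muscle genes and the gastric genes were chosen after their results were seen. In the extraocular and cardiac groups (4 arrays each), a value was singled out when its gap to the nearest other array exceeded a fixed share of the group's range (the value of Dixon's test), which chance gives in about 1 in 20 groups. Of 220 gene values tested, 22 stood apart (10%). In 12 of these the other 3 arrays lay at or under the floor and were given its value, and 10 were not of that kind. Of 8 array measures tested, 4 in each group, 3 stood apart. Groups of 3 arrays were not tested in this way.

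On extraocular muscle 2, Kit, Krt1, Krt8, Nppb and Sst stood above the other arrays, each with a ratio of 1 because the others were at the floor. Their values were 354, 272, 238, 294 and 294 against a floor of 208.5. The ratio was 0.981 for Clcn1 (275 on extraocular muscle 2) and 0.878 for Pfkfb1, which was lower there, at 307 against 1002 to 1181. Extraocular muscle 3 was high for Cd74 (0.927, 4104 against 2146 to 2251) and Klhl41 (0.856). Extraocular muscle 4 was low for Myh2 (0.872, 13347 against 20656 to 22019) and Myod1 (0.883), and just over the floor for Cartpt (1, value 222). Extraocular muscle 1 was low for Myl2 (0.844) and had the highest hexokinase 3' to 5' ratio (0.962, 2.39 against 1.06 to 1.11).

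On cardiac arrays the ratio was 1 for Aldoc and Kcnma1 (cardiac muscle 4), Ampd1 and Myf6 (cardiac muscle 3), and Cd24 and Mbp (cardiac muscle 2), with the other arrays at the floor. Cardiac muscle 2 was low for Rrad (0.88, 9688 against 13771 to 14445) and Eef1a2 (0.83), and cardiac muscle 1 for Gnb3 (0.868, 517 against 1259 to 1441). Cardiac muscle 2 also had the most probe sets above the floor (0.931, 73.6% against 67.8 to 68.2%) and the highest median (0.906, 609.2 against 479.1 to 491.3). Leaving out each cardiac array is part of the alternatives.

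Other splits of the arrays were counted for each comparison. Only the real split of the arrays gave as many called probe sets, 1 of 35, for extraocular against leg muscle (299, highest other 63), extraocular against cardiac muscle (569, highest other 1), extraocular against stomach smooth muscle (1757, highest other 1042), leg against cardiac muscle (691, highest other 40) and cardiac against stomach smooth muscle (1892, highest other 854). That share of 1 in 35 is the smallest these splits can give. A difference in processing between the tissues would give the same result, so the splits do not test it. For leg against stomach smooth muscle the 10 splits are too few for a share under 0.05 (1941, highest other 1). Among 100 drawn regroupings the real one alone gave as many probe sets for extraocular muscle (28, highest other 1), leg muscle (21, highest other 1), cardiac muscle (78, highest other 0) and stomach (552, highest other 0), and as many list calls (64, highest other 51). The number of list calls with the preset correlation thus came close to the real one under another grouping, though a regrouping can keep part of the tissue differences. The counts of 0 are limma counts at an adjusted p.

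The first pattern was that Acta1, Aldoa and the middle Gapdh probe set read far lower in leg than in cardiac muscle. A lower RNA level would lower all parts of Gapdh alike, but the log2 ratio of its 5' to its middle part was higher in leg muscle by 2.53 (3.14 ± 0.41 against 0.61 ± 0.84), which covers Gapdh and not Acta1 or Aldoa. Scanner saturation stays open as a candidate explanation, since the 3 probe sets read nearly the same value on each leg array, within a ratio of 1.003, against 1.186 or more on cardiac arrays, though this likeness was what prompted it. RNA degradation would lower the 5' part of a transcript most. On leg arrays the 5' part of Gapdh read 7286 to 9074, against 754 to 1066 for its middle part. That argues against degradation for the middle Gapdh probe set. The 3' to 5' log2 ratio of Gapdh was 0.18, -1.91 and -2.2 on leg muscle 1, 2 and 3. It was -0.09 to 0.11 on cardiac arrays. For Acta1 and Aldoa degradation stays open. The log2 ratio of the 3' to the 5' hexokinase control differed by -1.49 from cardiac muscle (-0.29 ± 0.07 against 1.2 ± 0.25, SD), against its direction. However, Hk1 itself differed between these tissues in 1 of 2 probe sets and the actin ratios of the tissues overlapped. A difference of the tissues in Acta1 and Aldoa was not tested.

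The second pattern was that smooth muscle genes stood higher in extraocular than in leg muscle, with a median of 0.83 (SD 0.84), but only 2 of 17 genes passed. The list's adjusted p, 0.043, ran from 0.00359 without leg muscle 1 to 0.286 with an estimated correlation, and was above the threshold without extraocular muscle 4 (0.185), with a replicate block (0.0807), with the floor at the 15th percentile (0.06) and with no filter (0.0661). More blood vessels in the extraocular samples would raise endothelial genes as well, but the endothelium list had a median of -0.14 (SD 0.49, 13 genes). Stomach RNA would bring its other bright transcripts. Of the 20 brightest genes of the stomach set at the floor on every leg array, 17 stayed under the level that the Actg2 share of 10.8% predicts on every extraocular array. The exceptions were Ptprf, Cds1 and Anpep. Membership of that set already required a level at least 2-fold lower in extraocular muscle. Many of the 20 were epithelial or gland genes, so they cannot speak to RNA of the stomach's muscle layer alone. Vessels with more wall muscle for the same endothelium, and a difference of the muscle tissue itself, stay open as untested, and the shift itself may be no more than a weak call.

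The third pattern was that gastric epithelium genes were high on arrays labelled as stomach wall without epithelium. Epithelium in only 1 of the 3 stomach samples is argued against, since the lowest array still had a median share of 0.763 of the highest (0.763, 1 and 0.872). That 13 of the 17 genes of the list were higher in stomach than in cardiac muscle restates the pattern, and 16 of the 17 lay above the floor on some array of another tissue. Krt8 and Sst averaged 17162 and 16003 intensity units on stomach arrays. Epithelium or glands left on the wall and expression by the wall itself cannot be told apart, since both would give these counts.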

How the results depend on the processing

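The alternatives were planned except 2, leaving out probe sets suspected of saturation and leaving out extraocular muscle 4 and stomach smooth muscle 1 together, which were chosen after seeing the data. No gene fold considered for the text reversed under the alternatives repeated for it. No list of extraocular muscle was called in opposite directions by the main test and an alternative. Lists that were not called could change direction, as the adipose list did against leg muscle, higher with camera and lower with fry. The direction of most called probe sets turned in the comparisons with stomach. For extraocular and for cardiac against stomach muscle, 45 and 43.8% were higher, but 51.6 and 52.4% with quantile normalization, 56.8 and 56.7% with median scaling, 50.6 and 50.6% without stomach smooth muscle 1, and 53.1 and 50.6% without the 2 arrays named above, and for leg against stomach muscle 43.3%, but 52.7% with median scaling. Of the gene folds considered for the text, 270 in all and including genes not named there, those called under every alternative repeated for single genes were 21 of 58 for extraocular against leg muscle, 55 of 61 against cardiac muscle and 66 of 67 against stomach, and 32 of 32, 21 of 21 and 30 of 31 for leg against cardiac, leg against stomach and cardiac against stomach muscle. Against leg muscle 27 lost their call without some single array, 23 of them without leg muscle 1 and 21 without leg muscle 2, and 26 lost it in a fit of only the tissues compared.

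A fold of at least 3 gave 141, 304 and 989 probe sets for extraocular against leg, cardiac and stomach muscle, 358 and 1134 for leg against cardiac and stomach muscle, 1000 for cardiac against stomach muscle, and 16, 46 and 342 for the sets of extraocular, cardiac and stomach muscle, as its stricter construction requires. A single probe set per gene tested 4187 and gave 157, 321, 1022, 420, 1103 and 1091 in the same order, and 11, 12, 43 and 313 for the sets of extraocular, leg, cardiac and stomach muscle, since fewer probe sets were tested. Fits of only the tissues compared gave 152 for extraocular against leg muscle, and 6, 0, 50 and 367 for the sets, with fewer arrays to estimate the spread. The 0 for leg muscle is a limma count at an adjusted p, and 72 met an unadjusted p.

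The leg muscle set (21) was 11 with median scaling, 6 with the floor at the 15th percentile, 35 with the floor at the 45th, 10 with no filter and 33 with array weights. The extraocular set (28) was 17 with the floor at the 15th percentile. Lists called fell from 64 to 16 with an estimated correlation and rose to 101 with fry, which asks another question. Apart from what the tests ask, the cause was not tested.

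Leaving out each array in turn gave 168 to 321 for extraocular against leg muscle (168 without leg muscle 2 and 176 without leg muscle 1), 14 to 32 for the extraocular set and 3 to 18 for the leg set. The lowest were 14 without leg muscle 1 and 3 without leg muscle 2. For the other results the counts without each array stayed within 1.5 times.

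A replicate block gave 285, 572, 1716, 684, 1976 and 1822 for the 6 comparisons. Between extraocular and leg muscle it ended the calls of the smooth muscle list (adjusted p = 0.0807, 0.00359 to 0.286 over the alternatives) and the nerve list (0.0755, 0.017 to 0.286 with camera and 0.0116 with fry) and gave one to the TCA and respiratory list (0.00536, 1.24e-04 to 0.767). Leaving out the suspected probe sets gave 300, 570, 1761, 686, 1939 and 1889, and leaving out the 2 arrays 357, 602, 1460, 738, 1822 and 1659. The former does not cover probe sets that read low alike on every array of a tissue. Quantile normalization, trimmed-mean scaling, the pseudocount, the strict filter, the absence of a fold minimum and the intensity trend kept every count within 1.5 times. Of the 31 list calls of extraocular muscle against the other tissues, 9 held under every alternative repeated for lists.

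The floor limits what low signals show. With the floor at the 45th percentile, 10 of 267 folds lost their call, and with it at the 15th, 13 of 270.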

Other observations

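The values of single arrays in this part were looked up after the data had been seen and were not tested, while the list of exocrine gland genes was fixed before. Single arrays held transcripts that no other array approached. On extraocular muscle 2 the 2 probe sets of Pip, a secretory protein gene, read 13367 and 11987, 31 and 17.4 times the highest other array, and Dnase1 read 4284 (8.5 times). On extraocular muscle 1 Spt1, a salivary protein gene, read 4769 (10.2 times) and Scgb2a1, a secretoglobin gene, 1764 (8.5 times). The fixed list of exocrine gland genes had a median of 0.08 between extraocular and leg muscle, with 1 of 13 genes higher. Against cardiac muscle its median was 0.2, with 2 of 13 higher. These medians are taken over all extraocular arrays, so they cannot tell whether single arrays held gland RNA, which was not tested.

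Kctd13 read 11222 on cardiac muscle 1, 6.2 times the highest other array. Stomach smooth muscle 1 had 31 probe sets at over 6 times every other array and stomach smooth muscle 3 had 1, while extraocular muscle 1 and 2 had 2 and 4.

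The abundant transcripts also varied among extraocular arrays. Acta1 and Aldoa read 607 and 607 on extraocular muscle 1 and 19581 and 40157 on extraocular muscle 4. The brightest probe set of an array ranged from 23075 to 49845.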
